A study of Mus musculus with 57 samples.

How the data were processed

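The values used are the processed log2 expression values that the authors deposited, 1 column for each of 57 arrays, and 0 columns were left unused. Per the submitters' processing notes, they were made with RMA in Partek 6.6. Per the labels' protocols, RNA was extracted with RNA STAT-60, and 100 ng of total RNA was labelled with biotin by the Affymetrix Two-Cycle method. Versions of the array description file, scan settings and batch dates are not given in the sources used here. Values ranged from 2.23 to 14.77, and 0 pairs of arrays were identical.

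Of 45101 probe sets, 34958 carried 1 gene, 932 several genes and 9211 none. Gene names were brought up to date with the supplied gene table, in which 34754 of the first kind were found, giving 18194 genes. For the 9012 genes with several probe sets, the probe set with the highest mean over all arrays was used. A gene was tested in a comparison when its log2 value was at least 5 in at least 3 of the arrays fitted.

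Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and adjusted p-values follow Benjamini and Hochberg. A gene was called at an adjusted p under 0.05 and an absolute difference of at least 1. Normal CPE stands for the postnatal and adult means averaged at equal weight. The comparisons were primary tumour with normal CPE, each of its ages and embryo controls, embryo control with normal CPE, adult with postnatal CPE, week 3 with week 2, and the 3 tumour groups with one another. Comparisons among normal groups pooled the spread of all normal arrays, and those among tumours that of the 3 tumour groups. Fits of primary tumours with either age held both ages, and the fit with embryo controls also held normal CPE. The medulloblastoma, a single array, was set against the range of all 46 carcinoma model arrays with a margin of 2. Tables and figures were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

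Before the values were seen, 32 gene lists with 554 genes were fixed, of which 515 lie on the array. They cover choroid plexus identity and transport, cilia, S phase, mitosis, p53 and FoxO targets, homologous recombination, the candidate oncogenes, TFIID and NF-Y, the targeted genes, Notch, Hedgehog, Wnt and BMP signalling, junctions, imprinted growth genes, neural and blood cell types, endothelium, fibroblasts, interferon, hypoxia, immediate early genes, and Y-linked genes with Xist. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether genes of a list move on balance one way, while its mixed form asks about either direction.

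Genes named in the text follow a rule fixed beforehand: the 12 largest increases and 12 largest decreases among called genes, up to 4 examples of each list, and 9 genes named always (Trp53, Rb1, Pten, Taf12, Nfyc, Rad54l, Ttr, Foxj1 and Mki67). Trp53 and Pten had no probe set with 1 gene in the values used and were not analysed here. For the medulloblastoma the rule was 8 genes on each side.

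For each array and chromosome, the median difference from mean normal CPE was taken relative to all autosomal genes, and primary tumours were set against normal CPE with an exact permutation test. The covariance of tumour and embryo differences was set beside simulated groups without change.

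Array sets were found after seeing the data: arrays with a title number up to 18 form set 1 and the others set 2. Comparisons within sets, the array set as a covariate, quantile normalization over all arrays, the genes common to all 3 normal groups and the grouping of passaged tumours by chromosome pattern were added after that. Alternatives fixed beforehand were centring of arrays, cyclic loess, other filters, other choices among probe sets, array weights, other eBayes settings, 1 common fit, other minimum differences, other controls and leaving out single arrays. The label each result received under an alternative follows the full calling rule, which replaced a rule on adjusted p alone after a first run.

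The code was tested on simulated data with 200 changed genes. Of these it found 95% at a change of 1.5 and 99% at 3 for primary tumours against normal CPE, 97% and 97% for embryo controls, and 93% and 100% for reimplanted tumours, with 1, 0 and 1 unchanged genes called. A chromosome lowered by 0.4 was found at -0.39. Probe sets without a gene name or with several were left out of the gene tests. No raw array files were read.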

Results

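Gene expression was measured on 57 Affymetrix arrays of mouse tissue. The tumours came from a mouse model of choroid plexus carcinoma that lacks Tp53, Rb and Pten, and comprised 13 primary tumours, 11 implanted tumours and 22 reimplanted tumours. One array of a medulloblastoma was present. Normal choroid plexus epithelium (CPE) of adult mice gave 3 arrays, labelled adult normal CPE. Another 4 arrays, 2 at week 2 and 2 at week 3, were labelled postnatal control. The 3 embryo controls came from embryonic day 18, and neither of these 2 class labels names a tissue. The postnatal controls are called postnatal CPE and counted as normal CPE here, an assumption that their class label does not settle. The labels gave a female nude host for primary, implanted and reimplanted tumours alike, and it is not clear from them whether primary tumours grew in that host. Normal samples and the medulloblastoma carried the floxed alleles without Cre. The number of arrays per group limits the precision of each comparison, and the p-values measure only the spread between these samples. All differences are log2 units, first group minus second, ± the standard error of limma. A gene was called at an adjusted p under 0.05 with a difference of at least 1. Where any array of the lower group lay under the filter limit of 5, near background, the difference is a bound and carries the sign ≥ or ≤, or the word about where arrays of both groups did. Ranks are those of the measured differences.

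Rb1 was the only 1 of the 3 targeted genes that could be followed on the arrays. Its mean was 7.97 ± 0.46 (SD) in primary tumours, 7.99 in implanted and 7.85 in reimplanted tumours, against 8.51 in adult CPE, 9.77 in postnatal CPE, 9.21 in embryo controls and 9.12 in the medulloblastoma. It was lower in primary tumours than in postnatal CPE (-1.79 ± 0.26) and embryo controls (-1.24 ± 0.28), and not called against adult CPE (-0.53 ± 0.30, adjusted p = 0.16). The position of its probes relative to the deleted part of the gene was not known here, so these values do not test the deletion. Trp53 and Pten were not analysed here.

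The normal CPE arrays of the 2 ages held different transcripts. The 2 groups differ in age and may also differ in tissue, which their labels do not settle. Adult CPE had more of the epithelial genes than postnatal CPE: Kl (≥ 9.97 ± 0.11, adjusted p = 3.34e-11), Slc13a4 (≥ 7.14 ± 0.16), Steap1 (≥ 7.12 ± 0.27) and Cldn2 (≥ 6.47 ± 0.68), a tight junction protein of the choroid plexus. Foxj1, the regulator of motile cilia, was higher by ≥ 4.71 ± 0.57. Postnatal CPE had more of the neural progenitor and glial genes Fabp7, Olig1 and Sox11 (differences -8.21 ± 0.27, ≤ -8.08 ± 0.26 and ≤ -7.76 ± 0.32) and more of the proliferation marker Mki67 (≤ -7.01 ± 0.27). Kl in postnatal CPE (mean 3.51) and Mki67 in adult CPE (4.08) were near background. Ttr, the transthyretin gene of the choroid plexus, lay at the top of the scale in both ages (14.05 postnatal, 14.60 adult). The highest value on any array, 14.77, was itself a Ttr value, so like expression of Ttr cannot be read from the normal and primary tumour groups. Of 13043 genes tested, 2432 were higher and 2452 lower in adult CPE.

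The choroid plexus identity list had 21 of 23 measured genes higher in adult CPE and 0 lower (camera adjusted p = 1.98e-07, and adjusted p = 0.4422 with an estimated correlation). Motile cilia genes had 23 of 26 higher and 1 lower (camera adjusted p = 7.4e-07, and adjusted p = 0.4422 with an estimated correlation), among them Rsph4a (≥ 5.56 ± 0.69) and Tekt1 (≥ 5.42 ± 0.42). Of the transport list, 15 of 17 were higher (camera adjusted p = 0.000608, and adjusted p = 0.4422 with an estimated correlation). Mitosis genes were lower in 34 of 35 cases (camera adjusted p = 2.48e-12, and adjusted p = 0.4422 with an estimated correlation) and S phase genes in 30 of 32 (camera adjusted p = 1.01e-08, and adjusted p = 0.4422 with an estimated correlation), with Top2a (≤ -6.80 ± 0.36) and Rrm2 (≤ -7.05 ± 0.18). Neural progenitor genes were lower in 13 of 15 cases (camera adjusted p = 1.1e-05, and adjusted p = 0.4422 with an estimated correlation), and the list mean was 10.24 ± 0.03 (SD) in postnatal and 6.11 ± 0.07 in adult CPE. Astrocyte genes were lower in 7 of 11 cases and higher in 2 (camera adjusted p = 0.0174, and adjusted p = 0.4422 with an estimated correlation). Immediate early genes were lower in 10 of 14 cases (camera adjusted p = 0.0019, and adjusted p = 0.4422 with an estimated correlation) and hypoxia genes in 10 of 16 (camera adjusted p = 0.0019, and adjusted p = 0.4942 with an estimated correlation). The choroid plexus identity mean spread from 7.13 to 9.42 among the 4 postnatal arrays and stayed within 12.33 to 12.36 among the 3 adult arrays.

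Between weeks 3 and 2 (2 arrays each) 53 genes were called, 25 higher and 28 lower at week 3. Macrophage genes led the lower ones: Ctss (≤ -4.53 ± 0.68, adjusted p = 0.0398), C1qb (≤ -4.38 ± 0.65), C1qa (≤ -4.04 ± 0.61) and Tyrobp (≤ -3.40 ± 0.53). Agmo (≥ 2.37 ± 0.28), Cdh19 (≥ 2.23 ± 0.28) and Rarb (≥ 2.13 ± 0.29) were higher. Of 15 macrophage genes measured, 4 were lower over all genes and 13 when adjusted over the list alone (camera adjusted p = 4.52e-16, and adjusted p = 0.4563 with an estimated correlation). Leaving out 1 array gave from 7 to 875 called genes. The spread in this fit was pooled over embryo, postnatal and adult arrays, so the standard errors do not measure the 4 compared arrays alone. Macrophage list means were 8.10 and 6.24 in the week 2 arrays and 5.01 and 4.30 in the week 3 arrays.

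Embryo controls had more vascular and ciliary transcripts than normal CPE, taken as the average of the 2 ages. Penk (≥ 8.02 ± 0.28, adjusted p = 1.32e-07), the enkephalin precursor, led the higher genes, followed by Klk4 (≥ 6.36 ± 0.44), Aplnr (≥ 5.60 ± 0.21) and Shh (≥ 4.96 ± 0.28). Alas2, of haem synthesis in red cells, was higher by ≥ 4.80 ± 0.13, and Foxj1 (≥ 2.77 ± 0.51) was also higher. The Foxj1 mean was 10.59 in embryo controls, 10.18 in adult and 5.46 in postnatal CPE, so its excess stood mostly against postnatal CPE. Mki67 differed by ≥ 1.03 ± 0.25 from the average, but its mean of 8.61 in embryo controls lay between 11.09 in postnatal and 4.08 in adult CPE. Scd1 (-4.81 ± 0.18) and Cox8b (≤ -4.16 ± 0.41) were lower. Of 13043 genes, 1339 were higher and 600 lower. In the second array set alone, described below, 1174 were higher and 676 lower.

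All 14 endothelial genes measured were higher in embryo controls (camera adjusted p = 2e-10, and adjusted p = 0.3419 with an estimated correlation), for instance Cdh5 (≥ 4.34 ± 0.17) and Emcn (≥ 3.81 ± 0.22). Motile cilia genes were higher in 23 of 26 cases (camera adjusted p = 4.86e-10, and adjusted p = 0.3419 with an estimated correlation), choroid plexus identity genes in 16 of 23 (camera adjusted p = 0.000556, and adjusted p = 0.6693 with an estimated correlation) and transport genes in 9 of 17, or 11 when adjusted over the list alone (camera adjusted p = 0.0065, and adjusted p = 0.659 with an estimated correlation). The means of both epithelial lists lay between the ages: 11.66 in embryo controls, 7.82 in postnatal and 12.35 in adult CPE for identity, and 11.34, 8.31 and 11.72 for transport. Imprinted growth genes were higher in 10 of 13 cases (camera adjusted p = 0.0092, and adjusted p = 0.5187 with an estimated correlation), with Igf2 (2.82 ± 0.52) and Meg3 (2.17 ± 0.32), and junction genes in 10 of 18 (camera adjusted p = 0.000473, and adjusted p = 0.4771 with an estimated correlation). Junction means were 7.90 to 8.05 in embryo controls, 7.79 to 7.88 in adult arrays and 4.99 to 6.51 in postnatal arrays, so that excess also stood mostly against postnatal CPE. BMP response genes (camera adjusted p = 0.0012, and adjusted p = 0.4771 with an estimated correlation), Hedgehog response genes (camera adjusted p = 0.0147, and adjusted p = 0.3419 with an estimated correlation), granule neuron precursor genes (camera adjusted p = 0.0191, and adjusted p = 0.3419 with an estimated correlation) and red blood cell genes (camera adjusted p = 0.0489, and adjusted p = 0.3419 with an estimated correlation) were called higher, with 6 of 15, 7 of 14, 3 of 10 and 2 of 3 members higher. Called lower were MHC class II genes (4 of 5, camera adjusted p = 0.0012, and adjusted p = 0.3419 with an estimated correlation), astrocyte genes (7 of 11, camera adjusted p = 0.0055, and adjusted p = 0.3419 with an estimated correlation), immediate early genes (7 of 14, camera adjusted p = 0.000777, and adjusted p = 0.3419 with an estimated correlation) and homologous recombination genes (camera adjusted p = 0.0269, and adjusted p = 0.7892 with an estimated correlation), although 0 of 21 members of the last list were called singly. Of these 4 lists only MHC class II lay below both ages (5.13 in embryo controls, 5.44 in postnatal and 7.36 in adult CPE). The other means lay between the ages and slightly above adult CPE: 7.19, 9.32 and 7.13 for astrocytes, 6.71, 8.80 and 6.63 for immediate early genes, and 5.89, 6.94 and 5.41 for homologous recombination.

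Against adult CPE, primary tumours were marked by proliferation. Mki67 (≥ 7.95 ± 0.19, adjusted p = 4.64e-17), Rrm2 (≥ 7.89 ± 0.25) of nucleotide synthesis, Top2a (≥ 7.15 ± 0.26) and Ccnb2 (≥ 7.04 ± 0.22) were higher, with Mki67 at 12.03 in tumours and at background in adult CPE (n = 13 and 3). Genes of ciliary and differentiated epithelium were lower: Tekt1 (≤ -5.08 ± 0.50), Dnah6 (≤ -4.47 ± 0.36), Foxj1 (-2.28 ± 0.60) and Kl (≤ -3.46 ± 0.94), with Slc7a10 (≤ -6.40 ± 0.58) and Tmprss11a (≤ -6.48 ± 0.53) among the lowest. Of 13685 genes, 1834 were higher and 1226 lower.

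All 35 mitosis genes were higher than in adult CPE (camera adjusted p = 9.57e-40, and adjusted p = 0.0624 with an estimated correlation), as were 31 of 33 S phase genes (camera adjusted p = 4.02e-30, and adjusted p = 0.0624 with an estimated correlation) and 15 of 21 homologous recombination genes (camera adjusted p = 1.71e-10, and adjusted p = 0.1871 with an estimated correlation). Cilia genes were lower in 22 of 26 cases and higher in 2 (camera adjusted p = 3.89e-12, and adjusted p = 0.1871 with an estimated correlation). Choroid plexus identity genes were lower in 9 of 23 cases and higher in 0 (camera adjusted p = 0.0018, and adjusted p = 0.6378 with an estimated correlation), and transport genes lower in 7 of 17 (camera adjusted p = 0.0053, and adjusted p = 0.5576 with an estimated correlation), with Fxyd1 (-3.97 ± 0.98) and Car2 (-3.47 ± 0.62). Interferon response genes were higher in 12 of 13 cases (camera adjusted p = 0.000169, and adjusted p = 0.4696 with an estimated correlation), immediate early genes in 11 of 14 (camera adjusted p = 0.00011, and adjusted p = 0.1042 with an estimated correlation) and FoxO targets in 7 of 17 (camera adjusted p = 0.0395, and adjusted p = 0.4135 with an estimated correlation). Hypoxia genes were higher in 9 of 17 cases without a call of the list (camera adjusted p = 0.0649).

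Against postnatal CPE the epithelial genes lay on the other side. Kl (about 6.51 ± 0.84), Steap1 (≥ 5.54 ± 0.39), Slc13a4 (≥ 5.27 ± 0.34) and Kcne2 (5.23 ± 0.53) were higher in primary tumours, while Olig1 (≤ -7.58 ± 0.42), Olig2 (≤ -6.75 ± 0.21), Fabp7 (≤ -6.73 ± 0.60) and Sox11 (≤ -6.32 ± 0.58) were lower (n = 13 and 4). Foxj1 (≥ 2.43 ± 0.53) was higher, and Mki67 passed the test with a difference under 1 (0.94 ± 0.17). Of 13685 genes, 2126 were higher and 1430 lower. Choroid plexus identity genes were higher in 21 of 23 cases (camera adjusted p = 2.15e-09, and adjusted p = 0.2806 with an estimated correlation) and neural progenitor genes lower in 11 of 15 (camera adjusted p = 5.69e-10, and adjusted p = 0.0652 with an estimated correlation). S phase genes were higher in 15 of 33 cases (camera adjusted p = 3.31e-06, and adjusted p = 0.3074 with an estimated correlation), mitosis genes in 10 of 35 (camera adjusted p = 0.000401, and adjusted p = 0.5666 with an estimated correlation) and cilia genes in 8 of 26, or 9 adjusted over the list alone (camera adjusted p = 0.0352, and adjusted p = 0.6146 with an estimated correlation). Notch pathway genes were lower in 9 of 16 cases (camera adjusted p = 0.000276, and adjusted p = 0.1498 with an estimated correlation), with Dll3 (≤ -3.31 ± 0.15) and Hes5 (≤ -2.58 ± 0.17). p53 targets were lower in 11 of 25 cases and higher in 4 (camera adjusted p = 0.00099, and adjusted p = 0.2892 with an estimated correlation), among them Eda2r (≤ -3.56 ± 0.49) and Cdkn1a (-1.68 ± 0.30).

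**Figure D1:**
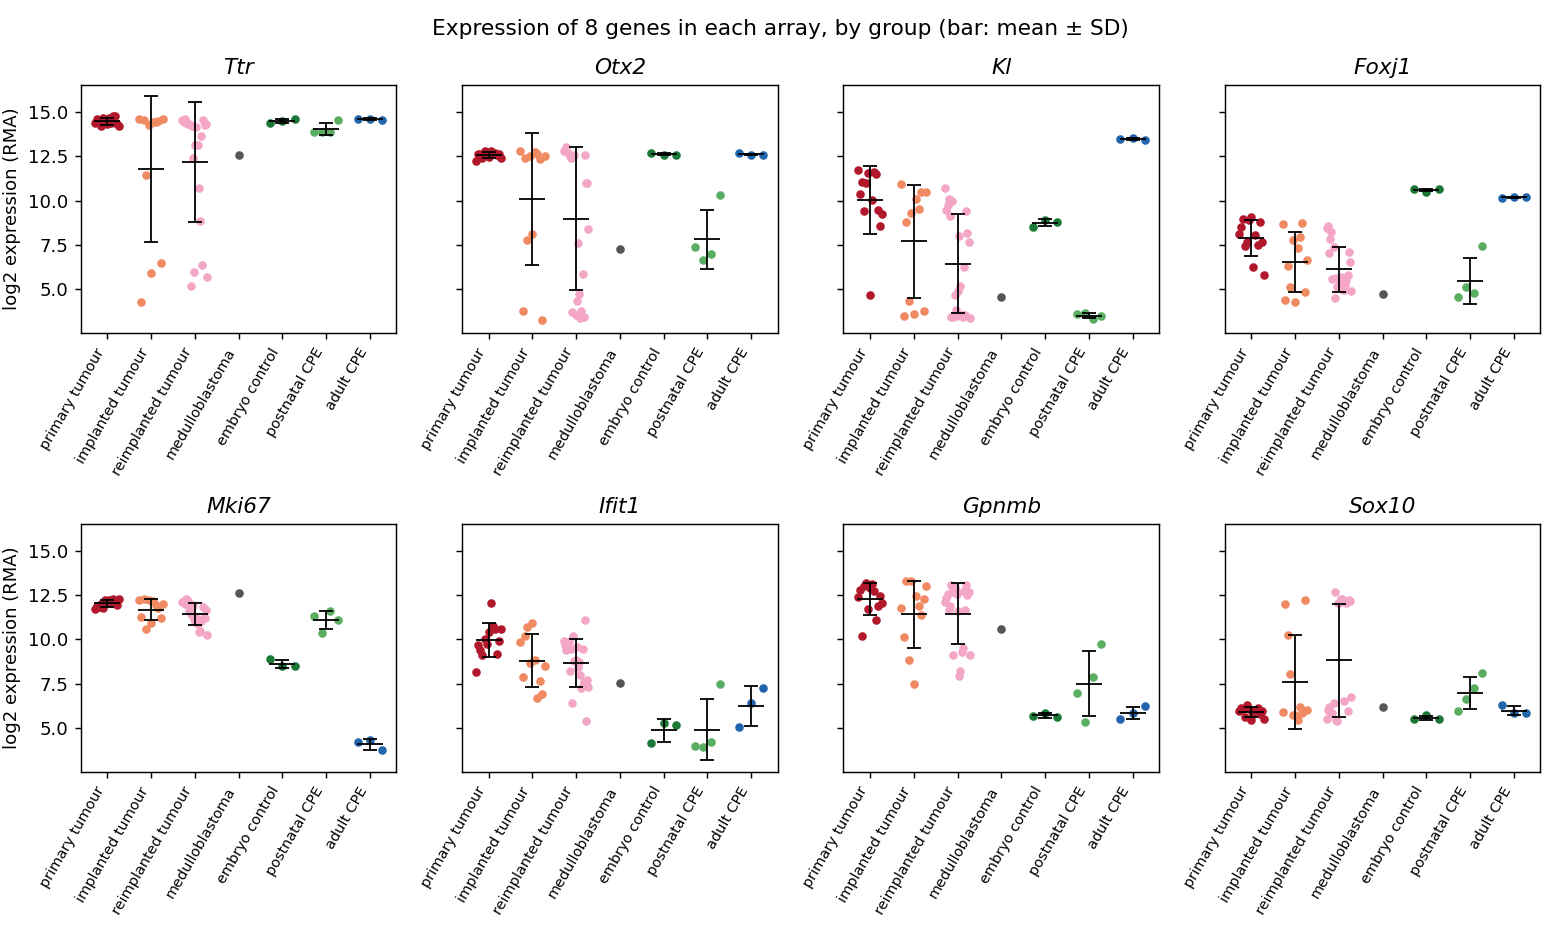
Log2 expression of 8 genes in each array by group. Ttr, Otx2, Kl and Foxj1 belong to the choroid plexus epithelium or its cilia, Mki67 to proliferating cells, Ifit1 to the interferon response, and Gpnmb and Sox10 are shown for the tumour groups.

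With the 2 ages of normal CPE averaged at equal weight, the genes farthest above normal in primary tumours were Gpnmb (5.61 ± 0.47, adjusted p = 4.99e-09), a glycoprotein of pigment cells and macrophages, Tspan10 (≥ 5.32 ± 0.50) and Slc39a8 (≥ 5.26 ± 0.38). Mki67 (≥ 4.44 ± 0.14, adjusted p = 8.86e-15) and Rrm2 (≥ 4.36 ± 0.18) of proliferation and Ifit1 (≥ 4.39 ± 0.50, adjusted p = 4.03e-07) of the interferon response were among the 12 largest increases. The largest decrease was that of Ccnd2 (-5.17 ± 0.33, adjusted p = 8.25e-11), a D-type cyclin, followed by Nap1l5 (≤ -4.29 ± 0.32), Slc35f1 (≤ -4.20 ± 0.21) and Kcnd3 (≤ -4.02 ± 0.33). Foxj1 was not called (≥ 0.08 ± 0.44). Of 13685 genes, 1566 were higher and 913 lower (n = 13 and 7).

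S phase genes were higher in 31 of 33 cases (camera adjusted p = 2.02e-23, and adjusted p = 0.1727 with an estimated correlation) and mitosis genes in 34 of 35 (camera adjusted p = 9.57e-29, and adjusted p = 0.1818 with an estimated correlation). Homologous recombination genes were higher in 14 of 21 cases (camera adjusted p = 2.3e-07, and adjusted p = 0.2428 with an estimated correlation), with Rad51ap1 (≥ 3.35 ± 0.17) and Brca1 (≥ 3.11 ± 0.16). All 13 interferon response genes were higher (camera adjusted p = 6.7e-07, and adjusted p = 0.2428 with an estimated correlation), among them Cxcl10 (≥ 4.27 ± 0.47), Usp18 (≥ 4.24 ± 0.43) and Oasl2 (≥ 4.05 ± 0.53). Macrophage genes were higher in 12 of 16 cases (camera adjusted p = 0.0057, and adjusted p = 0.5147 with an estimated correlation) and endothelial genes in 9 of 14 (camera adjusted p = 2.03e-06, and adjusted p = 0.2428 with an estimated correlation). Choroid plexus identity genes were higher in 16 of 23 cases and lower in 1 (camera adjusted p = 0.0014, and adjusted p = 0.5147 with an estimated correlation), with Otx2 (2.38 ± 0.32) and Tmem72 (≥ 2.22 ± 0.34). BMP response genes were higher in 8 of 15 cases (camera adjusted p = 0.0162, and adjusted p = 0.4359 with an estimated correlation). Cilia genes were lower in 10 of 26 cases and higher in 2 (camera adjusted p = 0.00021, and adjusted p = 0.457 with an estimated correlation), and Deup1 (≥ 4.44 ± 0.25), of centriole amplification, was among those higher.

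Neural progenitor genes were lower in 6 of 15 cases (camera adjusted p = 4.26e-05, and adjusted p = 0.2428 with an estimated correlation). Members of 3 pathway lists were lower: Notch in 3 of 16 cases (camera adjusted p = 0.0118, and adjusted p = 0.2428 with an estimated correlation), Hedgehog in 4 of 12 (camera adjusted p = 0.0162, and adjusted p = 0.2428 with an estimated correlation) and Wnt in 3 of 10 (camera adjusted p = 0.0318, and adjusted p = 0.4359 with an estimated correlation), with Ccnd1 (-2.61 ± 0.18) a member of the last 2. Each of these 3 lists had 1 member higher. Only Hedgehog genes lay below both ages (mean 7.29 in tumours, 8.14 in postnatal and 7.87 in adult CPE). That list also holds Ccnd2, the largest decrease of this comparison. Its mean therefore does not separate a Hedgehog response from the fall of these 2 cyclins, and it was not computed without them. The tumour means lay above adult and below postnatal CPE for neural progenitors (range 6.30 to 7.76 in tumours, mean 6.11 in adult and 10.24 in postnatal CPE), Notch (means 7.02, 6.78 and 7.92) and Wnt (6.29, 6.19 and 7.29). For neural progenitors the direction of the means thus turned with the control used. For Notch the lowest tumour array (6.80) lay within the adult range (6.77 to 6.81), so no clear turn can be read. For Wnt the excess over adult CPE was no larger than the median difference of all genes against adult CPE (0.12), so no turn can be read. Choroid plexus identity (11.40, 12.35 and 7.82) and cilia genes also lay between the ages, below adult CPE. The candidate oncogene list is given below with its genes. No call held for the lists of transport (5 higher, 1 lower of 17), p53 targets (2 and 3 of 25), FoxO targets (3 and 0 of 17), TFIID and NF-Y subunits (1 and 0 of 17), junctions and keratins (9 and 0 of 20, 10 higher when adjusted over the list alone), and imprinted growth genes (2 and 2 of 13). The same held for granule neuron precursors (1 and 2 of 12), neurons (1 and 1 of 11), astrocytes (2 and 5 of 11, 3 and 5 adjusted over the list alone), oligodendrocytes (1 and 2 of 8) and MHC class II genes (4 and 0 of 5). T cell genes (0 and 0 of 4), fibroblasts and matrix (4 and 2 of 16), hypoxia (5 and 3 of 17), immediate early genes (6 and 0 of 14) and the Y-linked and Xist list (0 and 0 of 4) were not called either. The targeted genes (1 measured) and red blood cells (2) were too few to test. For every other list of this comparison, the counts adjusted over the list alone equalled those over all genes.

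Over all lists and comparisons tested here, no camera call held with an estimated correlation. In fry, whose p tests whether the genes of a list move on balance one way, 21 lists were called for primary tumours against normal CPE, against 14 in camera. Unlike camera, fry does not set a list against the other genes. In this comparison 7543 of 13685 genes had an unadjusted p under 0.05 in limma, so many lists would pass fry. The 2 counts answer different questions, and fry does not back the camera calls. The fry values were 5.56e-12 for mitosis, 3.21e-07 for the interferon response and 0.000169 for choroid plexus identity.

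**Figure D2:**
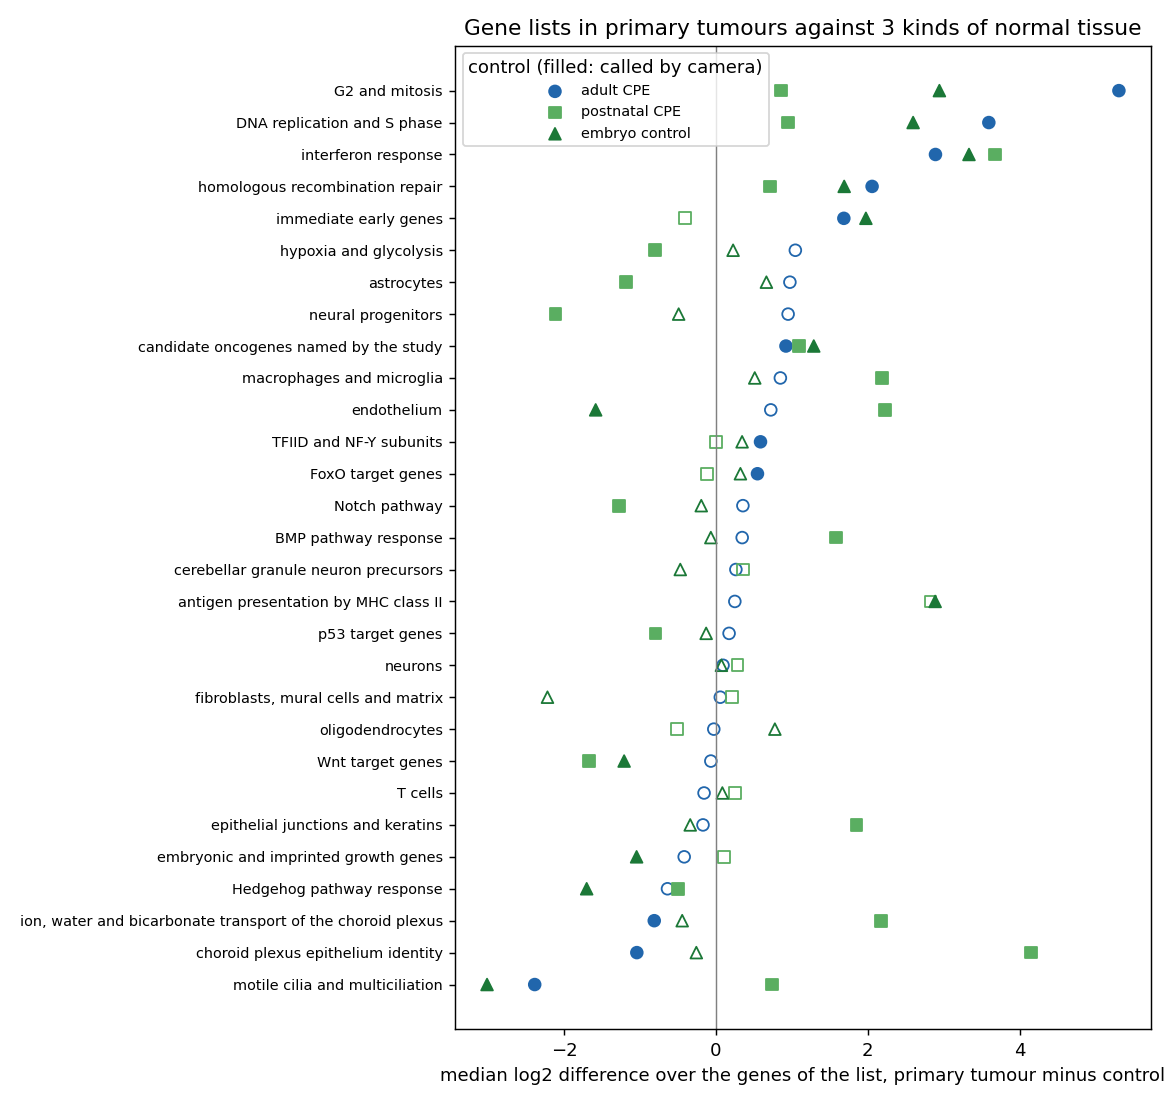
Median log2 difference of the tested gene lists between primary tumours and each of the 3 normal groups, filled where camera called the list. Lists of proliferation and the interferon response lie above 0 for all 3, and choroid plexus identity changes side between postnatal and adult CPE.

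Arrays formed 2 sets, seen only after the data were opened: set 1 held 17 arrays with means from 6.04 to 6.43, and set 2 held 40 arrays with means from 6.04 to 6.06. All postnatal and adult arrays lay in set 2, with 4 of the 13 primary tumours. The median difference of all genes was 0.14 for primary tumours against normal CPE, 0.11 against embryo controls, 0.12 against adult and 0.19 against postnatal CPE, and differences stand relative to these shifts. Splits into higher and lower genes depended on the scaling. For primary tumours against normal CPE, 1188 were higher and 1252 lower after centring each array, 1159 and 1284 after cyclic loess, and 1258 and 1183 after quantile normalization. Within set 2 the split was 1234 and 1305, and with the array set as a covariate 1256 and 1310.

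A gene set common to the 3 normal groups was added after the data were seen. In primary tumours 401 genes were called higher against embryo, postnatal and adult samples each, and 251 of these showed no overlap of arrays with any normal group. Independent lists would share 32.4 genes, but all 3 comparisons use the same 13 primary tumours, so that value is not what arises without change. They included Tspan10 (smallest of the 3 differences 5.15), Gpnmb (4.79), Usp18 (3.95), Ifit1 (3.72) and Cxcl10 (3.71). In the other direction 126 genes were lower against all 3 (12.8 for independent lists, with the same limit), among them Ccnd2 (smallest decrease 4.65) and Slc35f1 (3.73). Differences from groups near background are bounds here too.

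Against embryo controls, primary tumours were higher in Cox8b (≥ 8.08 ± 0.43, adjusted p = 1.13e-12), Gpnmb (6.58 ± 0.61), Lhx2 (≥ 5.68 ± 0.21), Cxcl10 (≥ 5.33 ± 0.61) and Ifit1 (≥ 5.10 ± 0.66) (n = 13 and 3). Cdkn2a, which encodes p16 and p19Arf, was higher by ≥ 4.97 ± 0.44, and Mki67 by 3.42 ± 0.19. Penk (≤ -7.35 ± 0.37, adjusted p = 6.23e-13), Shh (≤ -4.99 ± 0.24), Ccnd2 (-4.91 ± 0.43), Tekt1 (≤ -4.68 ± 0.48) and Foxj1 (-2.70 ± 0.57) were lower. Of 13806 genes, 1555 were higher and 1450 lower. The split was 1160 and 1846 after cyclic loess, 1323 and 1641 after quantile normalization, 1269 and 1684 within set 2 and 1389 and 1623 with the array set as a covariate. Set 1 held 1 embryo control.

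All 35 mitosis genes (camera adjusted p = 2.17e-27, and adjusted p = 0.0824 with an estimated correlation) and all 33 S phase genes (camera adjusted p = 2.13e-25, and adjusted p = 0.068 with an estimated correlation) were higher than in embryo controls, as were 16 of 21 homologous recombination genes (camera adjusted p = 3.85e-10, and adjusted p = 0.1361 with an estimated correlation). Interferon response genes were higher in 12 of 13 cases, 13 when adjusted over the list alone (camera adjusted p = 7.86e-06, and adjusted p = 0.2589 with an estimated correlation). Immediate early genes were higher in 10 of 14 cases (camera adjusted p = 5.48e-05, and adjusted p = 0.0824 with an estimated correlation) and MHC class II genes in 4 of 5 (camera adjusted p = 0.0021, and adjusted p = 0.231 with an estimated correlation). Cilia genes were lower in 22 of 26 cases (camera adjusted p = 1.99e-16, and adjusted p = 0.0824 with an estimated correlation) and endothelial genes in 13 of 14 (camera adjusted p = 3.59e-10, and adjusted p = 0.1361 with an estimated correlation), with Kdr (-2.28 ± 0.16) and Cdh5 (-2.36 ± 0.21). Hedgehog response genes were lower in 9 of 14 cases (camera adjusted p = 7.86e-06, and adjusted p = 0.068 with an estimated correlation), Wnt targets in 6 of 11 (camera adjusted p = 0.0019, and adjusted p = 0.1632 with an estimated correlation) and imprinted growth genes in 4 of 13, or 5 when adjusted over the list alone (camera adjusted p = 0.001, and adjusted p = 0.1461 with an estimated correlation). Shh and Ccnd2, named above among the decreases, are members of the Hedgehog list. Choroid plexus identity was not called, with 2 genes higher and 5 lower of 23 (camera adjusted p = 0.2772).

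The differences of primary tumours and of embryo controls from the shared normal CPE had a covariance of 0.127 over 13806 genes (r = 0.182). Simulated groups without change gave a mean of 0.013 and a highest value of 0.014, with a mean r of 0.385. They hold only the spread within groups. A departure of the postnatal arrays from all other groups would also add covariance through the shared controls and is not in them. A covariance above 0.014 therefore does not by itself show a likeness of tumours and embryo controls. Splitting the controls into 2 parts, each with postnatal and adult arrays, gave 0.0803 to 0.151 over 36 splits. Leaving out the cell cycle lists gave 0.127. Among 12946 genes tested in both, 349 were higher in both (139.9 for independent lists) and 244 lower in both (42.3). Opposite calls numbered 155 for genes lower in tumours and higher in embryo controls (89.4) and 66 for the reverse (66.2). The shared normal arrays alone raise the counts of genes called the same way above the values for independent lists. The covariance was 0.435 with adult and 1.07 with postnatal CPE as the sole control.

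The study names Taf12, Nfyc and Rad54l as oncogenes of this tumour. How that choice was made was not examined here. It may rest on the same tumours, so their values here are not taken as independent evidence. Rad54l, which acts in homologous recombination, was higher in primary tumours than in adult CPE (≥ 4.01 ± 0.24), embryo controls (3.12 ± 0.23) and postnatal CPE (1.09 ± 0.21). Nfyc, a subunit of the NF-Y factor, was higher than in postnatal CPE (1.57 ± 0.14) and differed by 0.78 ± 0.16 from adult CPE and 0.51 ± 0.15 from embryo controls, both under the minimum. Taf12, a TFIID subunit, was higher than in embryo controls (1.29 ± 0.14) and differed by 0.92 ± 0.15 and 0.67 ± 0.14 from adult and postnatal CPE. Against the averaged normal CPE the values were ≥ 2.55 ± 0.18, 1.17 ± 0.12 and 0.79 ± 0.11, and the list of 3 had 2 genes higher (camera adjusted p = 0.0057, and adjusted p = 0.2428 with an estimated correlation). The 17 TFIID and NF-Y subunits had a median of 0.29 in that comparison (camera adjusted p = 0.1139).

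Whole chromosomes differed between primary tumours and normal CPE in the median of their genes. Among 20 chromosomes, 6 were called by an exact permutation test, each higher relative to the median of all autosomal genes: 4 (0.14, adjusted p = 0.0135), 11 (0.09, adjusted p = 0.0135), 6 (0.09, adjusted p = 0.0135), 14 (0.07, adjusted p = 0.0144), 9 (0.05, adjusted p = 0.0135) and 2 (0.05, adjusted p = 0.0365). Large decreases of other chromosomes raise the rest on this relative scale, so these small increases may in part follow from it. With fewer control arrays, 0 chromosomes were called against adult CPE only, 0 against embryo controls and 2 against postnatal CPE only. Within set 2, which held all normal CPE arrays but only 4 of the 13 primary tumours, 2 were called. Against adult CPE, embryo controls and postnatal CPE in turn, chromosome 4 differed by 0.14, 0.14 and 0.13, chromosome 6 by 0.09, 0.11 and 0.08 and chromosome 11 by 0.06, 0.10 and 0.13. Chromosome 9 (0.0068, 0.0403 and 0.0953) and chromosome 14 (0.0467, 0.0162 and 0.0781) differed between the controls. Larger mean differences on chromosomes 1 (-0.20) and 7 (-0.20) were not called (adjusted p = 0.0723 each), since single tumours differed widely. Shifts beyond 0.25, a limit chosen after the table was seen, numbered 32 among 247 pairs of primary tumour array and autosome, 28 lower and 4 higher, in 12 of 13 arrays. Chromosomes 1 and 7 were lower in 5 arrays each, 19 in 4 and 18 in 3, and chromosome 4 was higher in 2. The largest shift in any normal CPE array was 0.14 and in any embryo control 0.08, while the medulloblastoma array ranged from -0.24 to 0.20, just inside the limit.

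Taf12, Nfyc and Rad54l all lie on chromosome 4. Among the 13 primary tumours, the shift of that chromosome rose with Taf12 (r = 0.758, permutation adjusted p = 0.006), Rad54l (r = 0.745, permutation adjusted p = 0.006) and Nfyc (r = 0.564, permutation adjusted p = 0.0422). Without the 2 farthest arrays the values were 0.835, 0.737 and 0.223. Within set 1 (9 arrays) r was 0.743, 0.720 and 0.651 in the same order (exact adjusted p = 0.0443, 0.0443 and 0.059).

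**Figure D3:**
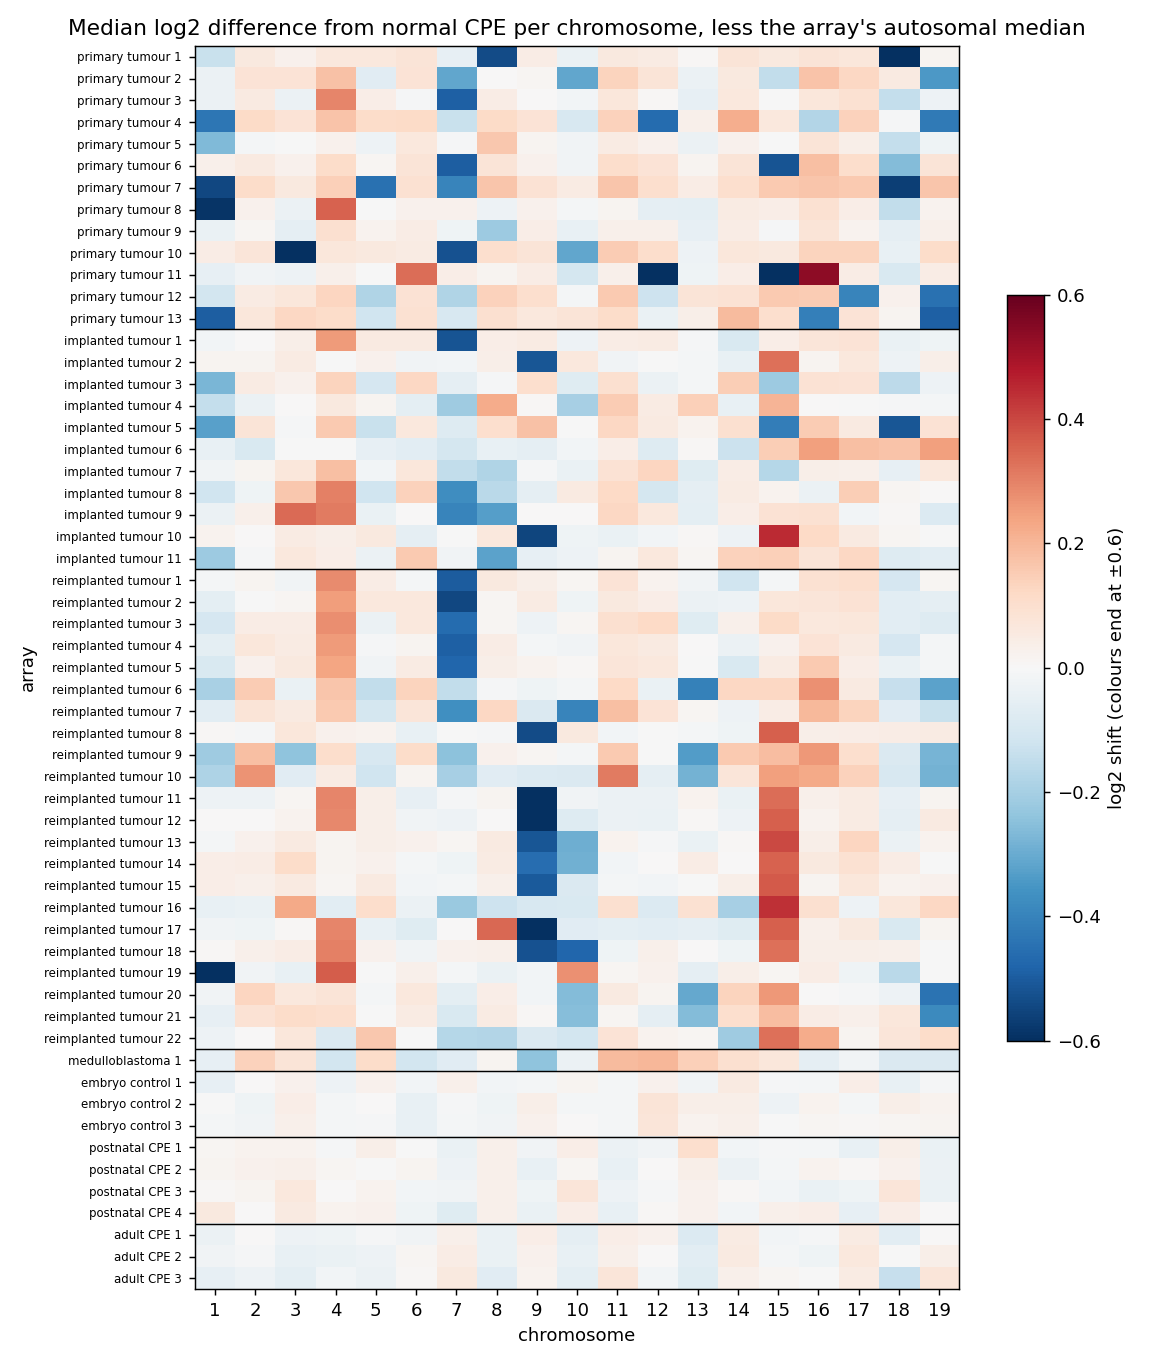
Median log2 difference of each autosome from normal CPE in each of the 57 arrays, relative to the median of all autosomal genes. Blocks of low or high values fall on whole chromosomes of tumour arrays.

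Implanted tumours differed from primary tumours in few genes. Vcan (about 3.46 ± 1.06, adjusted p = 0.049), a matrix proteoglycan, Cav1 (2.25 ± 0.53) and Fn1 (1.70 ± 0.49) were higher, and Krt8 (≤ -3.29 ± 0.74, adjusted p = 0.0169), an epithelial keratin, Kcnj13 (≤ -3.18 ± 0.92) and Kcnk1 (≤ -2.29 ± 0.69) were lower (n = 11 and 13). Ttr, at the top of the scale in primary tumours, differed by ≤ -2.71 ± 1.23 without a call (adjusted p = 0.15), and its SD among implanted tumours was 4.12. Of 14042 genes, 15 were higher and 79 lower, with a median of all genes of -0.13. The split turned with the scaling, with 6 higher and 4 lower after centring each array, 5 and 3 after cyclic loess, and 5 and 4 after quantile normalization. Within set 2 there were 3 called genes, and set 1 held 1 implanted tumour. Of the choroid plexus identity genes, 0 of 23 were lower over all genes and 16 when adjusted over the list alone (camera adjusted p = 0.000154, and adjusted p = 0.6699 with an estimated correlation).

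Reimplanted tumours had more matrix and glial transcripts and fewer epithelial ones than primary tumours. Col1a1 (4.11 ± 0.70, adjusted p = 7.87e-05), Vcan (about 4.46 ± 0.90) and Col3a1 (3.60 ± 0.61) of the matrix, Mbp (3.39 ± 0.87), Ugt8a (about 3.55 ± 1.04) and Sox10 (2.92 ± 0.88) of myelinating glia, and Egr2 (about 3.00 ± 0.77) were higher. Kcne2 (≤ -4.64 ± 0.99, adjusted p = 0.000583), Otx2 (≤ -3.62 ± 1.14), Kl (about -3.59 ± 0.91), Krt8 (≤ -3.45 ± 0.63) and Foxj1 (≤ -1.78 ± 0.45) were lower (n = 22 and 13). Within set 1 alone Col1a1 (2.78) and Col3a1 (3.55) were called, whereas Mbp (-0.0897), Sox10 (-0.0455) and Otx2 (0.21) had the opposite sign and Foxj1 differed by -0.081, all without a call. Mki67 (-0.58 ± 0.18), Taf12 (-0.40 ± 0.16), Nfyc (-0.41 ± 0.16), Rad54l (-0.72 ± 0.28) and Ttr (≤ -2.31 ± 1.05, adjusted p = 0.072) were not called. Of 14042 genes, 639 were higher and 883 lower, with a median of all genes of -0.12. The split depended on the scaling, with 779 higher and 708 lower after centring each array, 827 and 667 after cyclic loess, and 777 and 719 after quantile normalization. It was 49 and 147 within set 1, 528 and 522 within set 2, and 146 and 186 with the array set as a covariate. Transplants may share source tumours, which the labels do not record. Some pairs of passaged arrays were closer over all genes than any 2 primary tumours, whose highest correlation was 0.984. It was 0.996 for implanted replicate 1 with reimplanted replicate 1. For reimplanted replicates 14 and 15, 11 and 12, and 4 and 5 it was 0.992 each. Such arrays are unlikely to be independent tumours, so these p-values are likely too small.

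Choroid plexus identity genes were lower in 20 of 23 cases, or 22 when adjusted over the list alone (camera adjusted p = 9.78e-06, and adjusted p = 0.644 with an estimated correlation), transport genes in 11 of 17 (camera adjusted p = 0.0012, and adjusted p = 0.644 with an estimated correlation) and junction genes in 10 of 20 (camera adjusted p = 0.0094, and adjusted p = 0.5871 with an estimated correlation). Fibroblast and matrix genes were higher in 8 of 16 cases (camera adjusted p = 1.47e-05, and adjusted p = 0.4137 with an estimated correlation), oligodendrocyte genes in 7 of 10 (camera adjusted p = 6.58e-05, and adjusted p = 0.4137 with an estimated correlation) and macrophage genes in 3 of 17 (camera adjusted p = 4.7e-06, and adjusted p = 0.5871 with an estimated correlation). Interferon response genes were lower in 6 of 13 cases (camera adjusted p = 0.0265, and adjusted p = 0.644 with an estimated correlation), BMP response genes in 8 of 15, or 9 adjusted over the list alone (camera adjusted p = 0.0371, and adjusted p = 0.644 with an estimated correlation), and cilia genes in 7 of 22 (camera adjusted p = 0.0371, and adjusted p = 0.644 with an estimated correlation). Sox10 and Egr2 are also genes of Schwann cells. Olig2, of the oligodendrocyte lineage, lay under the limit of 5 in 20 of 22 reimplanted arrays, and Cdh19, of Schwann cells, lay above its highest primary value in 11, both chosen after their values were seen. Neural progenitor genes were higher in 4 of 13 cases and lower in 2 (camera adjusted p = 0.0265, and adjusted p = 0.4137 with an estimated correlation). Smaller shifts were called lower for mitosis (1 of 35 members, camera adjusted p = 0.002, and adjusted p = 0.644 with an estimated correlation), S phase (2 of 33, camera adjusted p = 0.0083, and adjusted p = 0.644 with an estimated correlation) and homologous recombination genes (0 of 21, camera adjusted p = 0.0265, and adjusted p = 0.644 with an estimated correlation), and higher for immediate early genes (2 of 14, camera adjusted p = 0.0265, and adjusted p = 0.5871 with an estimated correlation).

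The decrease of choroid plexus identity passed the test in set 2 only. There its mean differed by -3.13 between 17 reimplanted and 4 primary tumours (exact p = 0.002, adjusted p = 0.0086), and in set 1 by -0.27 between 5 and 9 (exact p = 0.1663). All 5 reimplanted arrays of set 1 had chromosome 7 low (-0.46 to -0.55) and chromosome 4 high (0.235 to 0.285), as did the implanted array of that set (-0.52 and 0.255), so they may not be independent tumours and do not show an effect of the array set. Reimplanted arrays of set 2 may not be independent either. Chromosome 9 was low with 15 high in 8 of them, and chromosomes 13 and 19 were low in 5. The exact and permutation p-values given here treat arrays as independent and may be too small. Fibroblast and matrix genes were higher in both sets, by 1.08 in set 1 and 1.71 in set 2 (exact adjusted p = 0.0162 and 0.0086). Oligodendrocyte genes differed by 0.25 in set 1 and 2.79 in set 2. Interferon response genes passed in neither set (-0.38 and -1.22, exact adjusted p = 0.4268 and 0.0777), and macrophage genes in set 2 only (0.10 and 1.28, exact adjusted p = 0.6239 and 0.0412). Mitosis genes differed by 0.40 in set 1 and -0.74 in set 2 (exact adjusted p = 0.0403 and 0.0162). Over the 22 reimplanted arrays the mitosis and identity means were related (r = 0.725, permutation adjusted p = 0.000725), and over the 17 of set 2 not past the test (r = 0.494, permutation adjusted p = 0.1083). Choroid plexus identity lay below the lowest primary tumour in 4 of 11 implanted and 16 of 22 reimplanted arrays. Below their lowest primary values lay Otx2 in 4 and 12 of these arrays, Ttr in 4 and 11, and Mki67 in 4 and 13, while Col1a1 lay above its highest primary value in 6 and 19 and Sox10 in 4 and 13. Between reimplanted and implanted tumours limma called 0 genes, and 1302 of 14042 had an unadjusted p under 0.05.

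**Figure D4:**
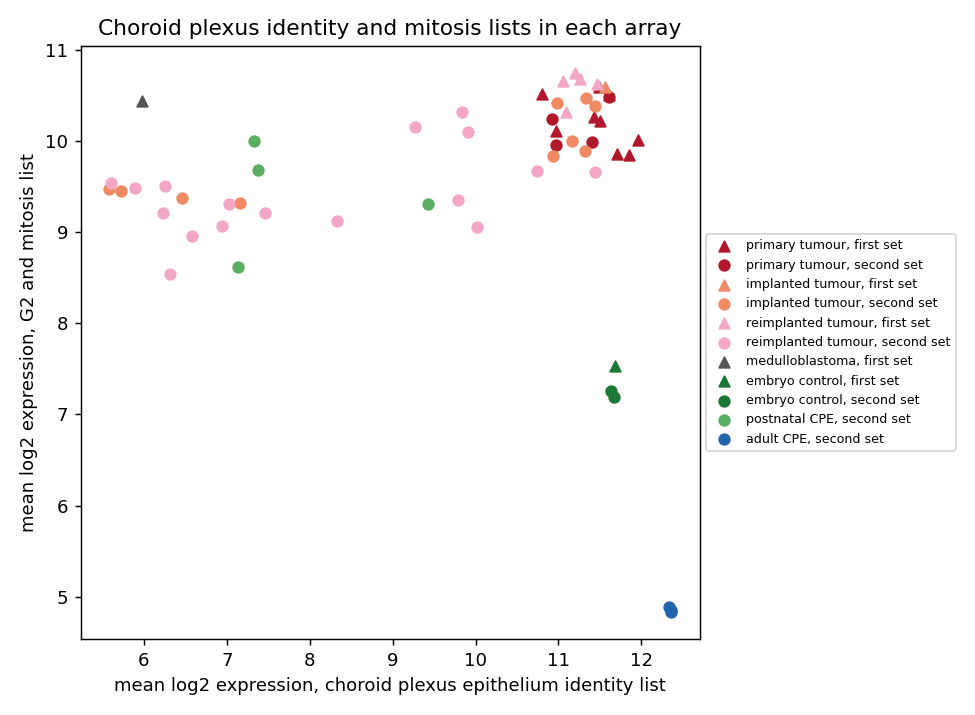
Mean of the mitosis list against mean of the choroid plexus identity list in each array, by group. Passaged tumours spread over a wider range of identity than of mitosis values.

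Shifts of whole chromosomes were also found in passaged tumours, 17 beyond 0.25 in 8 of 11 implanted arrays and 56 in all 22 reimplanted arrays. Patterns recurred. Chromosome 9 low with 15 high occurred in 2 implanted and 8 reimplanted arrays and 0 primary tumours, chromosome 7 low with 4 high in 3, 3 and 1, and chromosomes 13 and 19 low in 0, 5 and 0. These patterns were picked out after the shifts were seen, and reimplanted replicates 2 and 5 narrowly missed the limit for chromosome 4 (0.249 and 0.235) with chromosome 7 low. The 10 passaged arrays with chromosome 9 low and 15 high had a choroid plexus identity mean of 6.51 ± 0.91 (SD) and an oligodendrocyte mean of 9.22 ± 0.17. The 6 passaged arrays with chromosome 7 low and 4 high had 11.27 ± 0.23 and 6.07 ± 0.53 for the same lists. Primary tumours had 11.40 ± 0.37 and 5.75 ± 0.53.

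The medulloblastoma array lay at least 2 log2 units outside the range of all 46 tumours of the carcinoma model in 224 of 14912 genes, 169 above and 55 below. Farthest above were Dcx, a microtubule protein of migrating neurons (11.25, highest carcinoma 3.99), Insm1 (11.01) and Nhlh2 (9.82). Farthest below was Ccn2 (5.60, lowest carcinoma 9.76), with Col8a1 (4.94). Primary tumours held out 1 at a time gave 0 to 4 genes. The median list difference from primary tumours was 4.43 for neurons, 3.02 for granule neuron precursors, 1.86 for astrocytes, -5.91 for choroid plexus identity and -3.39 for transport. Set against all 46 carcinomas, its means lay inside the range for identity (5.97, lowest carcinoma 5.58), transport (7.10, lowest 6.65) and astrocytes (9.60, highest 10.22), and above it for neurons (10.02, highest 8.71) and granule neuron precursors (8.83, highest 7.56). Mki67 was 12.62 and Ttr 12.57 in the medulloblastoma. Atoh1, of the granule neuron precursor list, was near background there (3.60, primary mean 3.82), although the list as a whole was higher. With 1 array no test was made.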

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

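The tests of the 3 patterns below were chosen after the result was seen, apart from that on the 2 parts of each chromosome, and the splits of arrays were fixed before.

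Among 38 values tested for a lone postnatal array, about 1 in 20 groups would show one by chance. Postnatal replicate 4 stood apart in choroid plexus identity (9.42), transport (9.54), motile cilia (6.35), the interferon response (6.88) and Ttr (14.53). Postnatal replicate 2 stood apart in the candidate oncogene mean (8.14), neurons (5.76) and fibroblasts (5.63). The reimplanted minus primary difference itself differed between the array sets for 927 of 13878 genes, with 3909 at unadjusted p under 0.05. Of the probe sets without a gene name, 363 were higher and 241 lower in primary tumours among 4851 tested.

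The 4 postnatal CPE arrays held less of the choroid plexus transcripts than adult and embryo arrays. A plain shortage of choroid plexus cells in otherwise like tissue would shift all other cell types alike, whereas their list medians were 4.77 apart. Neural progenitor and glial cells in the postnatal tissue remain possible: both lists were higher in each postnatal array, but the decreases of the choroid plexus genes varied with an SD of 1.12, so this stays open. Endothelial means were lower in all 4 postnatal arrays (4.78 to 4.87, adult 6.29 to 6.58). Macrophage means were lower in replicates 1 to 3 (4.30 to 6.24, adult 7.01 to 7.19) and higher in replicate 4 (8.10). Quantile normalization left 4880 genes called. Both groups lay in set 2, whose array means already lay close together (6.04 to 6.06). The step could therefore change little and does not decide on the scaling. All 4 arrays lay below the lowest adult array, which a single swapped label would not give. Whether all 4 arrays hold tissue of another kind was not tested.

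Choroid plexus transcripts were low in part of the passaged tumours with a smaller and less uniform change in mitosis transcripts. Over the reimplanted arrays both were related (r = 0.725), but not past the test in set 2 (r = 0.494, permutation adjusted p = 0.1083), mitosis lay lower by 0.74 in set 2 and higher by 0.40 in set 1 (exact adjusted p = 0.0162 and 0.0403), and Mki67 lay below the lowest primary tumour in 13 of 22. RNA of host tissue without dividing cells would lower both alike, and the slope of mitosis on identity was 0.22 (0.13 to 0.31), under the 0.5 set for that explanation, which speaks against it as the whole decrease and leaves a smaller share open. That interval and the p-values treat arrays as independent, although transplants may share a source, so they may be too narrow and too small. Array set does not account for it, as the difference within set 2 was -3.13. Whether the 20 passaged arrays below the lowest primary tumour could be foreign or mislabelled tumours was not decided, because the labels tie no transplant to its source.

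Medians of whole chromosomes lay far from normal in single primary tumours, 32 times beyond 0.25. Without the called genes 30 of these stayed, and with quantile normalization 32 stayed. Each shift is a median over 342 to 1142 genes, less the median of all autosomal genes. A few strong genes or a shift of the whole array could hardly move it. Both counts were thus largely fixed by the measure and do not decide on a cause. Both parts of the chromosome shared the shift in 32 cases, which is what a change of the whole chromosome would give and is consistent with gained or lost copies. DNA was not measured.

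Other splits of the same arrays show whether chance can be excluded. For primary tumours against normal CPE, 1 of 100 splits, the real one, reached 2479 genes, and the highest other gave 961. Against embryo controls it was 1 of 100 (3005, highest other 629), for adult against postnatal CPE 1 of 35 (4884, highest other 3752), for implanted tumours 1 of 100 (94, highest other 51) and for reimplanted tumours 1 of 100 (1522, highest other 1). The splits for implanted and reimplanted tumours took no account of the array set or of source tumours that transplants may share. In set 1 lay 9 of 13 primary tumours, and in set 2 lay 10 of 11 implanted and 17 of 22 reimplanted tumours. These splits do not separate group from array set, and with the array set as a covariate 2 and 332 genes were called. For embryo controls against normal CPE 4 of 100 splits reached 1939, and 1 of them gave 2578. For reimplanted against implanted tumours the real count was 0, which all 100 splits reach by construction, so they test nothing there. A split with 1233 genes points to structure among these samples other than the group. List counts were less distinct. For primary tumours against normal CPE 10 of 100 splits reached 14 lists (highest other 16), against embryo controls 14 of 100 reached 13 (highest other 16) and for embryo controls against normal CPE 19 of 100 reached 14 (highest other 19), so chance could not be excluded for these 3 counts. For reimplanted against primary tumours 3 of 100 reached 14 (highest other 15).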

How the results depend on the processing

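No paired analysis was possible because replicate numbers only follow the order of deposit and no label links a transplant, a tumour or a normal sample to another. Groups of 3 or 4 arrays limit each comparison with normal tissue, primary tumours lie mostly in array set 1 and normal CPE in set 2, and no label says whether transplants share a source. Settings with array sets and quantile normalization, and the single controls for lists, covariance and chromosomes, were added after seeing the data. Where a value moved, the cause was not tested. In the following, differences are log2 units.

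Primary tumour against normal CPE gave 2479 called genes, 6667 with no minimum difference and 637 with a minimum of 2. With postnatal CPE as the only control it gave 3556, with adult CPE only 3060, and with implanted or reimplanted tumours in place of primary ones 1910 and 2368. Against embryo controls 3005 became 5823 and 1035 with no minimum and a minimum of 2, and 1294 in set 1, which holds 1 embryo control. Embryo control against normal CPE went from 1939 to 6075, 547, and 1058 in 1 common fit. Adult against postnatal CPE went from 4884 to 9518 and 2140 with the other minima.

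Week 3 against week 2 gave 53 called genes, 27 with unique probe sets only, 1 with array weights, 12 in 1 common fit and 15 with a minimum of 2. Leaving out 1 array gave 7 to 875: postnatal replicate 1 gave 239, replicate 2 gave 7 and replicate 3 gave 875. Implanted against primary tumours gave 94, but 10 after centring, 8 after cyclic loess, 9 after quantile normalization, 2 in set 1 (1 implanted array), 3 in set 2, 2 with the array set as a covariate, 216 in 1 common fit, 619 with no minimum and 10 with a minimum of 2. Reimplanted against primary tumours gave 1522, but 196 in set 1, 332 with the covariate, 5761 with no minimum and 323 with a minimum of 2.

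With an estimated correlation the lists called fell to 0 from 14 (primary tumour against normal CPE), to 0 from 13 (against embryo controls), to 0 from 14 (embryo control against normal CPE) and to 0 from 14 (reimplanted against primary). The medulloblastoma count of 224 became 821 against primary tumours only and 766 with a margin of 1. The covariance of 0.127 became 0.101 without a filter, 0.435 with adult and 1.07 with postnatal CPE only, and 0.102 to 0.167 with 1 array left out (postnatal replicates 2 and 4). Of the 6 chromosomes called, 1 was called with all tumours, 3 without the called genes, 2 in set 2, 0 with adult, 2 with postnatal CPE only and 0 against embryo controls, and 3 to 6 with 1 array left out (adult replicate 2 gave 3).

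Some genes changed sign. For primary tumour against normal CPE, with postnatal CPE only: Tekt1 (0.34), Psrc1 (-1.18) and Klf6 (-0.29). With adult CPE only: Olig1 (0.50), Grm5 (0.17), Otx2 (-0.0203), Tmem72 (-0.0864), Atp2b3 (-0.73), Slc4a5 (-1.79), Hes5 (0.28), Lef1 (-0.45), Smad6 (-0.47), Dsg2 (-0.69), Cldn2 (-1.57), Hmga2 (0.90), Olig2 (0.27), Fabp7 (1.48), Gad1 (0.41), Ugt8a (0.0278) and H2-Aa (-0.33). With implanted tumours in place of primary ones: Otx2 (-0.14), Krt18 (-0.0541), Atp2b3 (-0.18), Slc4a5 (-1.20), Cldn2 (-0.63), Plagl1 (-0.40) and Ugt8a (0.38). With reimplanted tumours in place: Otx2 (-1.24), Tmem72 (-0.89), Krt18 (-1.23), Atp2b3 (-0.74), Slc4a5 (-2.03), Lef1 (-0.16), Id1 (-0.72), Cldn1 (-0.55), Dsg2 (-1.43), Cldn2 (-1.50), Plagl1 (-1.39), Zic5 (-0.0381), S100b (0.64), Cldn11 (0.44), Ugt8a (1.90) and Dcn (0.30). With all tumours as 1 group: Slc4a5 (-0.85), Dsg2 (-0.17), Cldn2 (-0.40), Plagl1 (-0.42) and Ugt8a (0.53).

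For embryo control against normal CPE, Cenpf became -0.0507 with the mean of all probe sets. In set 1 alone, with 1 implanted array, implanted against primary tumours changed sign for Vcan (-0.67), Fez1 (-0.54) and Map3k21 (0.36), and reimplanted against primary tumours for Mbp (-0.0897), Otx2 (0.21), Clic6 (0.13), Krt18 (1.02), Deup1 (0.72), Rsph1 (0.28), Zmynd10 (0.53), Tyms (0.18), Ccnb2 (0.45), Perp (0.000291), Myc (-0.34), Id1 (0.32), Cldn1 (0.58), Nes (-0.17), Zic1 (0.0825), Syt1 (0.17), S100b (-0.24), Gfap (-1.19), Gja1 (0.37), Sox10 (-0.0455), Cldn5 (-0.39) and Pfkp (0.18). The median of chromosome 9 became -0.10 with all tumours.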

Other observations

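In primary tumours Dct (≥ 5.56 ± 0.76), of melanin synthesis, was higher than in postnatal CPE and not called against adult CPE (means 9.65 and 8.39). Against embryo controls Scd1 (5.23 ± 0.37), of fatty acid desaturation, and Fndc1 (≥ 6.31 ± 0.41) were higher, and Lum (≤ -4.41 ± 0.70), Dcn (≤ -4.20 ± 0.67) and Col1a1 (-3.62 ± 0.42) lower. Against adult CPE, Acta2, of smooth muscle and myofibroblasts, was higher by 3.32 ± 0.79, while Lum (≤ -4.71 ± 0.73) and Dcn (≤ -4.29 ± 0.70) were lower.

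In reimplanted tumours Krt18 (≤ -3.41 ± 1.11), Cldn1 (≤ -3.19 ± 1.03), Id1 (-2.46 ± 0.66) and Msx1 (-1.94 ± 0.48) were lower than in primary tumours. Within set 1 the sign of Krt18 (1.02), Cldn1 (0.58) and Id1 (0.32) was the opposite, without a call. Hmga2 (1.72 ± 0.52), Myc (1.58 ± 0.48) and Sox11 (about 2.66 ± 0.75) were higher, but within set 1 Myc had the opposite sign (-0.34) and none of the 3 was called.

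Hypothesis 1: the passaged tumours with low choroid plexus identity derive from few source tumours. All 10 passaged arrays with chromosome 9 low and 15 high lay below the lowest primary tumour in choroid plexus identity, and their oligodendrocyte means ranged from 9.02 to 9.55. The 6 arrays with chromosome 7 low and 4 high included 0 such arrays, the 5 with chromosomes 13 and 19 low included 5, and the other 12 included 5. Reimplanted replicates 2 and 5 count among these 12 only because chromosome 4 narrowly missed the limit (0.249 and 0.235), and all 5 reimplanted arrays of set 1 had chromosome 7 low. This would be consistent with shared sources, but the 20 arrays below the lowest primary tumour hold more than 1 pattern. A record that ties each transplant to its source would test it.

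Hypothesis 2: part of the higher expression of Taf12, Nfyc and Rad54l in primary tumours follows the dosage of chromosome 4, on which all 3 lie. The shift of chromosome 4 was related to Taf12 (r = 0.758) and Rad54l (r = 0.745) across primary tumours, and the 32 shifts beyond 0.25 that both parts of a chromosome share may reflect whole copies. Nfyc depended on 2 arrays (r = 0.223 without them). The mean shift of chromosome 4 was 0.14, whereas Rad54l differed by ≥ 2.55 ± 0.18, so dosage alone would not suffice for Rad54l. The differences of Nfyc and Taf12 from averaged normal CPE, given above, also exceeded that mean shift. Copy number measured in the same tumours would test it.

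Hypothesis 3: the averaged normal CPE mixes a proliferating postnatal tissue with a resting adult one, so that the side on which choroid plexus identity falls depends on the control. Age need not be what separates these tissues. Olig2 was 10.36 in postnatal CPE, 3.33 in adult CPE and 3.42 in embryo controls. Identity means of embryo controls (11.64 to 11.68) lay above all postnatal ones (7.13 to 9.42). Whether the postnatal arrays hold tissue of another kind was not tested. With postnatal CPE only, 21 of 23 identity genes were higher in primary tumours, and with adult CPE only 0 were higher and 9 lower. Postnatal arrays differed in the decrease from adult values, with means of 5.25, 5.63, 5.30 and 2.73 over 16 genes, and the SD over genes of 1.12 leaves open whether other cells in the tissue could explain it. Staining of postnatal tissue for a progenitor marker would test it.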
